A study of Mus musculus with 44 samples.

How the data were processed

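Single cells sorted as osteomacs were profiled by RNA sequencing. Osteomacs are macrophages that reside on bone surfaces. The labels describe cultures of neonatal calvarial cells from C57BL/6J mice, kept for 16 h with or without 50000 megakaryocytes, from which CD45-positive, F4/80-positive and CD41-negative cells were sorted. CD41, encoded by Itga2b, is a megakaryocyte and platelet surface protein, so that gate is meant to leave megakaryocytes out. Whether it did could not be checked, since Itga2b is not among the genes listed. Cells were captured on a Fluidigm C1 chip, cDNA was made with a SMART-Seq kit, libraries with a Nextera XT kit, and 150 b paired-end reads were taken on a NextSeq instrument, per the labels. The genome build was mm10 and Seurat was used, per the submitters' processing notes. The aligner, the read counter and the annotation are not given in the sources used here.

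One table with 3613 genes and 44 cells was used, and no column of it was left out. Its deposited values are a signal with the form of RPKM: reads of the gene × 1e+09, divided by the library reads of the cell and by a whole number that is the same for that gene in all 44 cells. That form was worked out from the values, since the table has no header that states it. The whole number per gene had no relation to annotated gene length (Spearman correlation across 3472 genes −0.02), so deposited values compare cells within a gene and not genes with each other. The most frequent value of each cell gave its library reads, which lay within 0.0003 of a whole number, and the smallest whole divisor per gene then turned all 99807 values above 0 into whole reads, at a tolerance of 0.0001. Divisors found from the other 43 cells gave whole reads for every value of each left-out cell, over 500 genes drawn from those read in at least 20 cells. CPM below means recovered reads × 1e+06 / library reads, both inferred in this way, and is not a deposited unit. 25 genes are listed at 0 in all 44 cells and 7 gene names have been turned into dates by a spreadsheet. How the authors chose the genes they listed is not stated, and mitochondrial genes are not among those listed, so the mitochondrial share of reads was not analysed here.

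The study was designed here before the data were examined, with read counts in mind. The deposited unit is a signal instead, for which the design named the means of the deposited values. Because the reads came back whole, sums of reads per group were kept as the main value and the means of the deposited signal are given beside them for Emb and Alcam, the genes in the series title. The rule for named genes was applied to CPM, and the genes that the same rule named on the deposited signal are given too. No count model was fitted.

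Cells were grouped by the treatment field of the labels: 20 cells with megakaryocytes, all from plate 7, and 24 cells without megakaryocytes, all from plate 3. The titles of the cells without megakaryocytes carry the same culture abbreviation as the others, with megakaryocytes in it, which conflicts with the treatment field. No label names a culture or an animal, so each group counts as 1 sample, cells are not replicates, and no test between the groups, p-value, standard error or number of changed genes was made. Shares of cells have exact Clopper-Pearson 95% intervals. Summed reads have exact Poisson 95% intervals, and ratios of sums have exact binomial 95% intervals. These intervals cover counting error only. They take reads as independent, although the reads carry no molecular identifiers and are not independent molecules. They are therefore likely too narrow even for that error. Where a group had no read of a gene, a floor of 3 reads over the group was used and the fold is a lower bound. SDs are between the cells of a group. Differences are with megakaryocytes minus without, in the mean over cells of log2(CPM + 1).

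Named genes followed a rule fixed before the data were examined. Emb, Alcam and the sort-marker genes Ptprc, Adgre1 and Itga2b were always named, except that Itga2b is not among the genes listed. Among the 3271 genes with a read in at least 10 of the 44 cells, the rule took the 12 highest and the 12 lowest differences whose share of cells and pooled level differed in the same direction, the pooled level by at least 2-fold, and passed over predicted and mitochondrial genes. It added the 3 members with the largest absolute difference in each gene list described, of which 1 is not reported here. The 30 gene lists were also fixed beforehand. A list with at least 5 tested members has a median difference, set against 10000 random lists of the same size matched on mean level. That places the list among the genes of these cells as a description. It takes genes as independent and is not a test of the groups. Cells were not clustered and no cell was removed. No doublet caller was run on 44 cells.

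Alternatives were a higher detection limit, thinning of each cell to 310000 reads, leaving out the 2 cells with under 1/3 of their group's median library reads, means in place of sums, other pseudocounts and filters, and each cell left out in turn. Size factors from scran were planned and not run. Scaling by median ratios and by listed reads took its place. Reads and divisors were recovered from a simulated table with known answers: 44 of 44 library totals and the reads of 3184 of 3184 genes read in at least 10 cells, and of 373 of 387 genes read in fewer, came back exactly. That table was built in the inferred form from the recovered totals and divisors. It shows that the code inverts that form, not that the deposited values have it. Of 100 genes simulated with a fold of 2 between groups, 75 had the simulated direction, and of 100 with a fold of 8, 100 had it. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used. Gene coordinates come from GENCODE M21, which is on the same genome build.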

Results

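The series asks how megakaryocytes affect osteomacs, and its title names embigin (Emb) and CD166 (Alcam) as raised by them. The table holds 44 single cells, 20 labelled as cultured with megakaryocytes and 24 as cultured without. The first are called with-MK cells here and the second without-MK cells. All with-MK cells come from plate 7 and all without-MK cells from plate 3, so the plate, the capture and the treatment cannot be told apart. The titles of the without-MK cells name megakaryocytes as well, against their treatment field. With 1 culture per group at most known, the values below have no replicate check. They describe these cells and not the conditions. Where a pair of values is given, with-MK cells come first.

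Library reads per cell had a median of 834834 in with-MK cells, from 69181 to 1212604, and of 527930 in without-MK cells, from 270537 to 714465. The sums were 15639246 and 12415448 reads. The 3613 listed genes took a median of 76.4% of a with-MK cell's reads and 64.4% of a without-MK cell's. A with-MK cell had reads in a median of 2054 listed genes and a without-MK cell in 2492, although the latter were sequenced less deeply. The 50 most abundant listed genes held a median of 29.4% and 19.8% of the reads. Actb alone held 7.68% and 3.40%, and ribosomal protein genes 0.992% and 1.39%. With-MK cells 11 and 16 were the shallowest, with 69181 and 71585 reads. Cell 16 also had the lowest Actb share, 0.845%, and 245233 CPM of the nuclear RNA Malat1, against a group median of 6623.

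The genes of the surface proteins used for the sort separated the plates. Ptprc, which encodes CD45, had reads in 20 of 20 with-MK cells (95% interval of the share from 83.2% up) and in 1 of 24 without-MK cells (4.17%, 0.105 to 21.1%). The sums were 8206 reads (8029 to 8386) and 1 read (0 to 6). Adgre1, which encodes F4/80, had reads in 17 of 20 with-MK cells (85.0%, 62.1 to 96.8%) and in 1 of 24 without-MK cells, with 7780 reads (7608 to 7955) and 1 read (0 to 6). After each cell was thinned to 310000 reads, which left out 2 cells of each group, Ptprc had reads in 17 of 18 with-MK and 0 of 22 without-MK cells, and Adgre1 in 16 of 18 and 1 of 22. The 0 of 22 cells allow a share of up to 15.4% at the 95% level. Ptprc lies on chromosome 1 at 138062861 to 138175708 (minus strand) and Adgre1 on chromosome 17 at 57358691 to 57483527 (plus strand), both as protein-coding genes of the mm10 build.

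Macrophage and stromal transcripts split the cells the same way. The 19 listed genes of the macrophage list summed to a median of 21713 CPM in with-MK cells, from 2948 to 53535, and to 95.6 in without-MK cells, from 1.92 to 906. The 5 listed genes of the osteoblast and fibroblast list, Col1a2, Col3a1, Postn, Sparc and Mgp, summed to a median of 7.03 in with-MK cells, from 3.88 to 154, and to 6286 in without-MK cells, from 924 to 89671. The ranges did not overlap for either list. The macrophage list has 24 members, of which 19 are listed. The osteoblast and fibroblast list has 20, of which only 5 are listed. Sparc, a collagen-binding matrix protein, had 56 reads in with-MK cells (42 to 73) and 75589 in without-MK cells (75051 to 76130). Each of the 20 with-MK cells had at least 1 Sparc read and none had more than 7. The share of cells with a read therefore carries no information for Sparc. No gene of the dendritic, lymphoid, erythroid, endothelial and mast cell lists, or of the mitosis list, was among the genes listed. How the listed genes were chosen is not stated, so this does not show that such cells are absent.

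**Figure D1:**
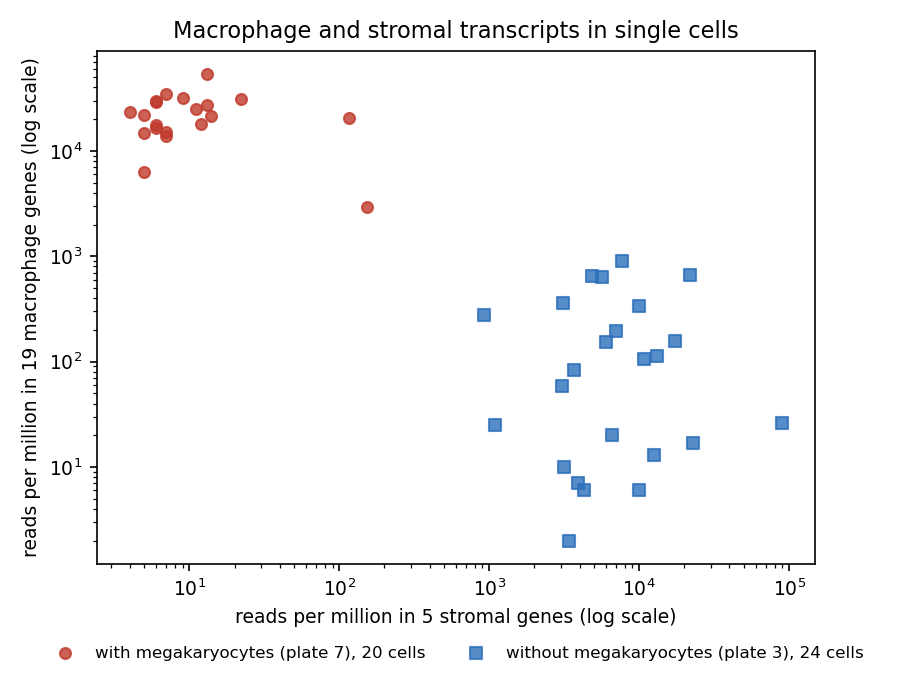
CPM in 19 macrophage genes (vertical axis) against 5 osteoblast and fibroblast genes (horizontal axis), both on log scales, with 1 point per cell. The 20 with-MK cells lie between 2948 and 53535 on the vertical axis and the 24 without-MK cells between 1.92 and 906.

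Emb was higher in with-MK cells and Alcam was at a similar level in both groups. Emb encodes embigin, an immunoglobulin-superfamily adhesion protein, and lies on chromosome 13 at 117208536 to 117274415 (plus strand). It had reads in 20 of 20 with-MK cells (from 83.2% up) and in 16 of 24 without-MK cells (66.7%, 44.7 to 84.4%). Its sums were 17454 reads (17196 to 17715) and 1326 reads (1256 to 1399), or 1116 and 107 CPM. The pooled level was 10.4-fold higher in with-MK cells (9.88 to 11.1), a log2 ratio of 3.39. The mean of log2(CPM + 1) was 9.52 ± 1.61 (SD over 20 cells) and 4.09 ± 3.35 (SD over 24 cells), a difference of 5.44. In the deposited signal, the mean was 44390 ± 33061 and 3776 ± 5832. Thinned to 310000 reads, Emb had reads in 18 of 18 with-MK cells and in 15 of 22 without-MK cells. The without-MK cells had few or no reads of most macrophage genes, with Lgals3 (2051 reads, in 20 of 24 cells) and Cd68 (215 reads, in 13) as the main exceptions, so this comparison sets cells with macrophage transcripts against cells with stromal transcripts.

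Alcam encodes CD166, another adhesion protein of that superfamily, and lies on chromosome 16 at 52248996 to 52454074 (minus strand). It had reads in 13 of 20 with-MK cells (65.0%, 40.8 to 84.6%) and in 19 of 24 without-MK cells (79.2%, 57.8 to 92.9%). Its sums were 2705 reads (2604 to 2809) and 2201 reads (2110 to 2295), or 173 and 177 CPM. The ratio was 0.976 (0.922 to 1.03), so no difference in the pooled level of Alcam was detectable beyond counting error. As for Emb, cells with macrophage transcripts are set against cells with stromal transcripts. The ratio therefore does not show whether Alcam changed in macrophages. The mean of log2(CPM + 1) was 4.69 ± 3.77 and 5.33 ± 3.42, a difference of −0.63. In the deposited signal, the mean was 11284 ± 18864 and 12574 ± 19497. With-MK cell 13 held 36.2% of the group's Alcam reads. Without the cell with the most Alcam reads in each group, the levels were 116 and 151 CPM. Scaling by median ratios instead gave a log2 ratio of 0.22, so the sign of the Alcam difference depends on the scaling. Thinned to 310000 reads, Alcam had reads in 12 of 18 with-MK and 17 of 22 without-MK cells.

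**Figure D2:**
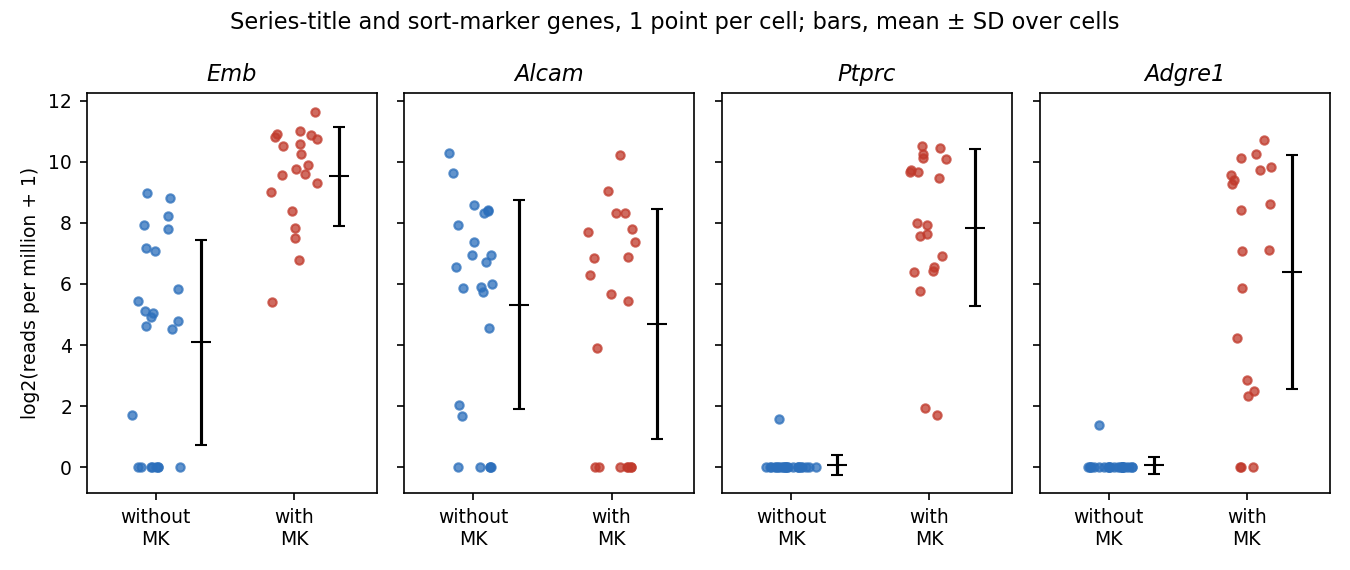
Log2(CPM + 1) of Emb, Alcam, Ptprc and Adgre1 in each of the 24 without-MK and 20 with-MK cells, with the mean and SD over the cells of a group. Emb has reads in all 20 with-MK cells, Alcam is spread alike in both groups, and Ptprc and Adgre1 have 1 read each over all without-MK cells.

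The 12 genes with the highest differences were genes of leukocytes and macrophages, and each had reads in at least 19 of 20 with-MK cells. They were Cd53, Lyz2, Lilrb4a, Tyrobp, Lcp1, Ctss, Msr1, Laptm5, Fcgr3, Ccr1, C3ar1 and Ms4a6d. The leukocyte tetraspanin Cd53 led with a difference of 10.98, at 3093 CPM in with-MK cells and 0.403 in without-MK cells (48380 and 5 reads). Lyz2, the lysozyme of macrophages and granulocytes, reached 7914 and 2.01 CPM, a 3930-fold ratio (2662 to 6074). Tyrobp, the adaptor of activating receptors, had 27557 and 3 reads, a ratio of 7292 with a counting interval of 2495 to 35363. The scavenger receptor Msr1 had 30786 and 2 reads, and the chemokine receptor Ccr1 had 17796 and 1. The low-affinity Fc receptor Fcgr3 had 22428 reads in with-MK cells and none in without-MK cells, at least 5935-fold higher against a floor of 3 reads over the group. The inhibitory receptor Lilrb4a was 362-fold higher (293 to 454) and the lysosomal protein Laptm5 383-fold (287 to 524).

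The 12 genes with the lowest differences were Lox, Cald1, Ncs1, Mfap5, Pdpn, Il1rl1, Enc1, Ptrf, Hbegf, Bgn, Map1b and Hmga2, several of them genes of matrix and of contractile cells. Each had reads in at least 23 of 24 without-MK cells. Lox, the enzyme that crosslinks collagen and elastin, had 6 reads in with-MK cells, or 0.384 CPM, and 32408 reads in without-MK cells, or 2610 CPM, a difference of −10.56. The actin-binding caldesmon gene Cald1 had 0.575 CPM in with-MK cells and 1288 in without-MK cells, and the microfibril gene Mfap5 0.384 and 2122. Bgn, a proteoglycan of bone and connective tissue, had 1.98 and 1619. Il1rl1, which encodes an interleukin receptor, had reads in 24 of 24 without-MK cells, with 0.320 and 1912 CPM. Pdpn, which encodes podoplanin, was 22.3-fold lower in with-MK cells (21.5 to 23.2), at 168 and 3740 CPM, the smallest pooled ratio among the 12. Single cells set the size of several of these ratios. Without the cell with the most reads of a gene in each group, the ratio moved by more than 1.5-fold for 32 of the 88 genes named by the rule and its list part, and its direction changed for 1, Creld2. Lilrb4a went from 8.50 to 12.38, Laptm5 from 8.58 to 11.54 and Pdpn from −4.48 to −6.74 as log2 ratios. Among the other named genes, the ratio moved away from 0 for Ptrf (−4.67 to −10.26), Enc1 (−7.79 to −11.70), Hbegf (−5.16 to −8.36), Il1rl1 (−12.55 to −13.61), C3ar1 (10.04 to 11.50), Ms4a6d (10.98 to 12.04), Msr1 (13.58 to 14.44), Lcp1 (12.63 to 13.43), Cxcl2 (8.43 to 9.71), Slc11a1 (7.33 to 8.14), Oas1a (9.26 to 9.91), Zfp36 (4.66 to 5.25), Tgfbr1 (−0.27 to −1.25), Id3 (−2.56 to −3.17) and S100a8 (6.24 to 9.10). It moved towards 0 for Ccr1 (13.79 to 11.98), Ptprc (12.67 to 10.88), Adgre1 (12.59 to 10.72), F13a1 (12.83 to 10.78), Rtp4 (11.39 to 9.25), Trf (11.15 to 8.64) and Stab1 (9.75 to 8.50), which have 1 read or none in the without-MK cells. Where the only read was left out, the sum of 0 was set to the floor of 3 reads, which by itself lowers the ratio. Such ratios are lower bounds, and the floor sets part of their shift. For Ptprc the with-MK level moved only from 525 to 476 CPM. Stab1 was at the floor before and after. These genes are counted among the 32. The same rule on the deposited signal named Cd52, Csf1r, Ccl9, Hpgds, Ncf4, Aif1, Ccl4, AI607873, Cyth4, F13a1, Itgam and Gpr141 as highest, of which it shares 0 with the 12 above. As lowest it named Lox, Il1rl1, Mfap5, Hbegf, Cald1 and Map1b, which are 6 of the 12 above, and Cfl2, Wwtr1, Ncam1, Nckap1, Adam12 and Fbln2. Csf1r, the receptor for macrophage colony-stimulating factor, had reads in 20 of 20 with-MK and 5 of 24 without-MK cells.

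**Figure D3:**
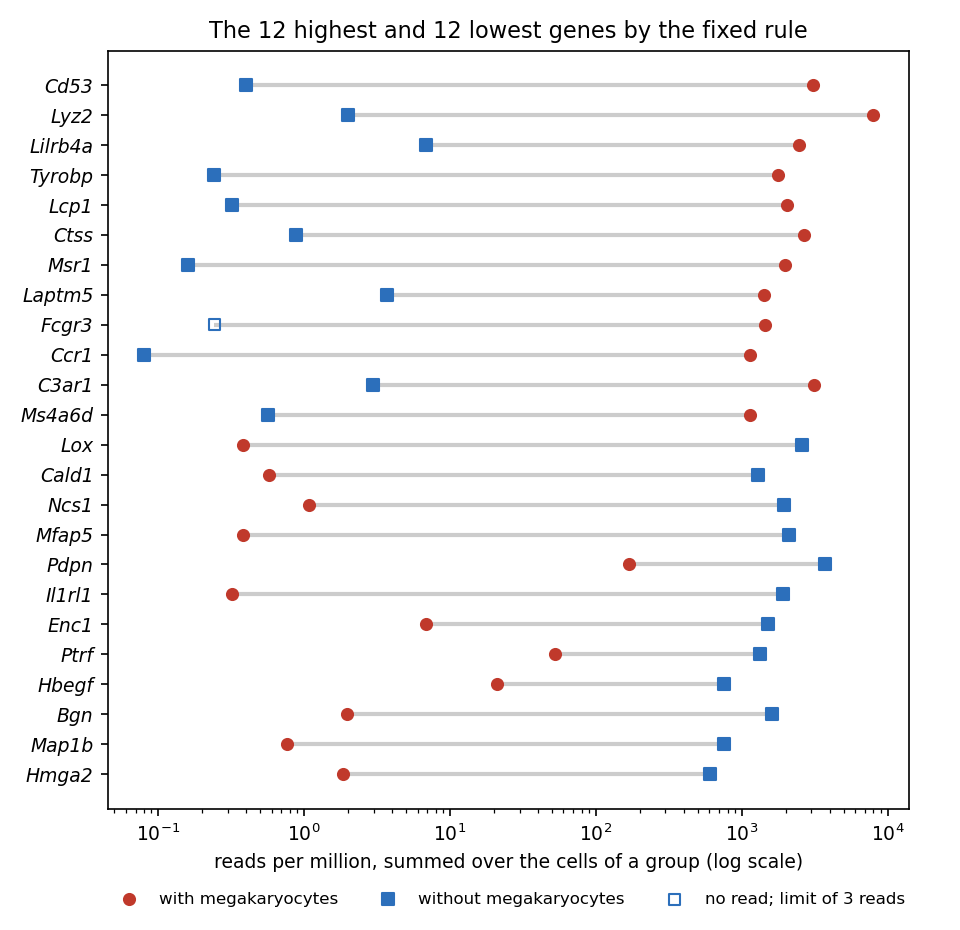
CPM from reads summed over the cells of each group, on a log scale, for the 12 genes with the highest and the 12 with the lowest difference. Fcgr3 has no read in without-MK cells and is drawn at the limit of 3 reads, and Pdpn shows the smallest gap, with 168 and 3740 CPM.

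Over the 3271 genes tested, the median difference was −1.10, while the median log2 ratio of pooled levels was −0.14, so list medians are set against random lists, which centre near −1. Of the 18 lists with at least 5 tested members, 8 had medians above and 2 below the central 95% of random lists, and 8 lay within it. Higher and lower below refer to the mean log level, and for 28 of the 197 list members, 13 of them respiratory chain genes, the pooled level went the other way. All list differences set cells with macrophage transcripts against cells with stromal transcripts. The lists are not separate results, since some share members. The uptake and macrophage lists share Trem2, C1qb, C1qc and Fcgr1. Genes of macrophages and of their uptake and degradation functions were higher in with-MK cells. All 19 tested genes of the macrophage list were higher, with a median difference of 6.34, above 10000 of 10000 random lists. Lyz2, Tyrobp and Ctss led, and Ctss, a lysosomal protease, stood at 2666 and 0.886 CPM. Of 14 genes for uptake of particles and dying cells, 12 were higher and 2 lower, with a median of 4.65. Msr1, Fcgr3 and the complement gene C1qb, with 16611 reads and none, had the largest differences, and the lower members were Mfge8 and Itgav. Of 19 lysosomal genes, 18 were higher and 1, Cd63, lower, with a median of 2.14. Laptm5, the protease Lgmn (78.8-fold, 70.2 to 88.8) and the progranulin gene Grn (25.1-fold, 23.3 to 27.1) led. Without the top cells, the log2 ratios of Lgmn and Grn were 7.73 and 5.53, against 6.30 and 4.65.

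All 8 tested antigen presentation genes were higher in with-MK cells, with a median of 4.38. They were led by Cd74, the invariant chain, at 1064 and 17.2 CPM, by Psmb8, at 176 CPM with no read in without-MK cells, and by the class I gene H2-K1, at 399 and 22.4. With-MK cell 6 held 86.3% of the group's Cd74 reads, and without it the level was 153. Without-MK cell 21 held all Cd74 reads of its group. All 11 tested interferon-stimulated genes were higher, with a median of 2.70. Rtp4 (217 and 0.0805 CPM), Oasl2 (154 and 0.242) and Oas1a (98.7 and 0.161) led. Of 13 lipid genes, 10 were higher and 3 lower, with a median of 2.36. The cholesterol exporter Abcg1 was 24.1-fold higher (22.0 to 26.4), the scavenger receptor Cd36 481-fold (323 to 750.5) and Apoe 31.4-fold (28.4 to 34.8). Of 10 inflammatory genes, 7 were higher and 3 lower, with a median of 2.29. The chemokine genes Ccl3 (884 and 0.242 CPM), Cxcl2 (999.6 and 2.90) and Ccl4 (820.2 and 0.161) led, and Ptgs2, Ccl7 and Cxcl16 were the lower members. Ccl7 was lower by its mean log level only, since its pooled level was 3.02-fold higher (2.94 to 3.09), at 1975 and 655 CPM. Of 8 iron and haem genes, 6 were higher and 2 lower, with a median of 1.44. The ferritin gene Fth1 stood at 11915 and 1374 CPM, Slc11a1 at 273 and 1.69 and Trf at 183 and 0.0805.

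Stromal and matrix genes were lower in with-MK cells. All 5 tested osteoblast and fibroblast genes were lower, with a median of −7.14, above 2 of 10000 random lists. Sparc stood at 3.58 and 6088 CPM, the collagen gene Col1a2 at 2.43 and 3967 and Postn at 0.512 and 771. Without cell 13 the without-MK level of Col1a2 was 1834, and its log2 ratio went from −10.67 to −9.65 without the top cells. Of 10 genes for matrix proteases and their inhibitors, 6 were lower and 4 higher, with a median of −3.03, above 45 of 10000 random lists. The inhibitors Timp1 (9.46 and 2181 CPM) and Timp3 (0.895 and 1348) and the matrix glycoprotein Thbs1 (719 and 5264) had the largest differences. The higher members were Mmp12, Adam8, Adam17 and Spp1, of which Spp1 was lower on pooled levels.

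**Figure D4:**
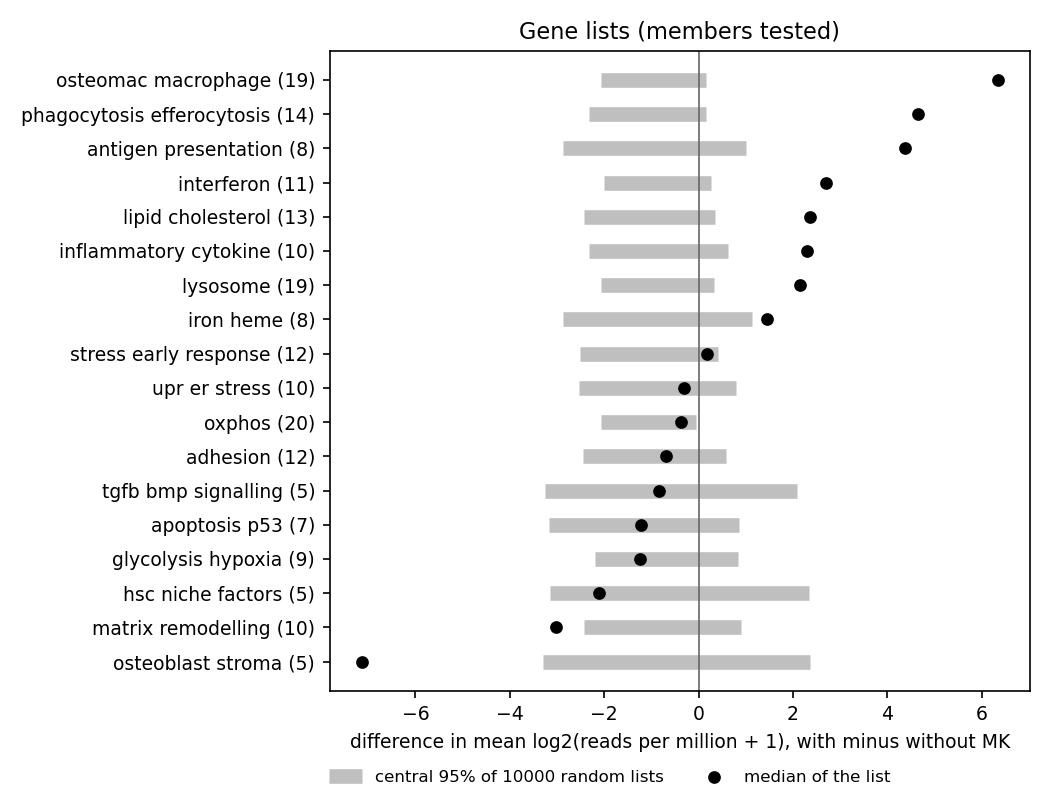
Median difference in mean log2(CPM + 1), with-MK minus without-MK cells, for the 18 lists with at least 5 tested members (points), with the central 95% of 10000 random lists (grey bars). The macrophage list lies at 6.34 and the osteoblast and fibroblast list at −7.14.

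The other 8 lists lay within the range of random lists. Of 5 factors that support haematopoietic stem cells, 4 were lower in with-MK cells and 1, Spp1, higher, with a median of −2.12. The Notch ligand Jag1 stood at 58.5 and 897 CPM and Ptgs2 at 182 and 733. Spp1, which encodes osteopontin, had a difference of 3.38 but a pooled ratio of 0.502 (0.493 to 0.510). Without-MK cell 13 held 57.9% of its group's Spp1 reads, and without the cell with the most reads in each group the log2 ratio was still −0.45. Igf1, counted as lower, had a pooled level 1.35-fold higher (1.30 to 1.41), at 371 and 274 CPM. Of 12 adhesion genes, 5 were higher and 7 lower, with a median of −0.70 that turned to 0.13 on pooled levels. Its largest differences were those of the integrins Itgam (637 and 0.161 CPM) and Itgb2 (482 and 10.1) and of Emb. Of the 24 without-MK cells, 1 had 10 CPM or more of Itgb2, and without the top cells its log2 ratio went from 5.58 to 7.73. Of 20 respiratory chain genes, 18 were lower by the mean log level, with a median of −0.38, and the median was 0.23 on pooled levels. Uqcrc1 stood at 233 and 330.0 CPM and Ndufb9 at 199 and 204. Of 9 glycolysis genes, 7 were lower and 2 higher, with a median of −1.24. Ldha stood at 472 and 1074 CPM, Pgk1 at 21.7 and 33.6 and Hk2 at 786 and 1003.

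Of 12 immediate early and heat shock genes, 6 were higher and 6 lower. Zfp36 (574 and 22.6 CPM) and Dusp1 (348 and 93.2) were higher and Dnajb1 (7.55 and 107) was lower. The median of 0.17 was below 0 under 4 of 9 alternatives: −0.01 on thinned cells, −0.04 without the 2 shallow cells, −0.06 with listed reads as the total and −0.16 on the deposited signal. Of 10 unfolded protein response genes, 4 were higher and 6 lower, with a median of −0.32 that turned to 0.05 on pooled levels and to 0.06 with median ratio size factors. Atf4 stood at 258 and 445 CPM, Manf at 149 and 271 and Creld2 at 106 and 92.1. With-MK cell 2 held 66.2% of its group's Creld2 reads. Of 7 apoptosis and p53 genes, 2 were higher and 5 lower, with a median of −1.22 that turned to 0.31 on pooled levels. Bcl2a1b had 2369 reads in with-MK cells and none in without-MK cells, Gadd45b stood at 21.0 and 105 CPM and Mdm2 at 164 and 401. Of 5 genes of the TGF-beta and BMP pathways, 1, Id2, was higher and 4 lower, with a median of −0.85. Id3 stood at 93.3 and 549.6 CPM, Id2 at 1600 and 420.0 and Tgfbr1 at 41.8 and 50.3.

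Lists with 1 to 4 tested members have no median. Of the osteoclast genes, Tcirg1 (242 and 11.7 CPM) and Tnfrsf11a, with 3453 reads and none, were higher, and Clcn7 differed by less than counting error (1.03-fold, 0.913 to 1.16). Pf4, the only megakaryocyte and platelet gene listed and one that tissue macrophages express too, had reads in 16 of 20 with-MK and 5 of 24 without-MK cells, at 1694 and 0.483 CPM. With-MK cell 7 held 28.8% of its group's Pf4 reads, at 8749 CPM. That cell had 2.29 CPM of Ptprc and no read of Adgre1, but 31898 CPM in the macrophage list. The source of the Pf4 reads was not tested. Of the neutrophil genes, Mmp8 stood at 1370 and 0.483 and S100a8 had 2094 and 22 reads, the latter mostly in 1 cell (90.9%), while S100a9 had 14 and 5 reads, a ratio of 2.22 (0.757 to 7.89). The monocyte genes F13a1 (586 and 0.0805) and S100a4 (3.51-fold, 3.18 to 3.89) were higher. So were all 3 alternative activation genes, F13a1, Mrc1 (1050 and 4.19) and Stab1, with 3259 reads and none. Without-MK cell 16 held 94.2% of its group's Mrc1 reads, and the log2 ratio went from 7.97 to 11.71 without the top cells. The S phase genes Pcna (55.7 and 106) and Cdt1 (16.9 and 32.5) were lower.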

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

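The scalings by median ratios and by listed reads, the use of the deposited signal for gene lists, and all alternatives for named genes other than Emb and Alcam were chosen after the data were seen, and the rest before. The shares of cells with a read of Emb and of Alcam stayed within their exact intervals at 5 reads, at 10 CPM, on thinned cells, without the 2 shallow cells and with each cell left out. Leaving out a single cell could not move a share out of intervals this wide, so for the shares that setting is no check. Emb stayed higher in with-MK cells throughout. Its log2 ratio of 3.39 was 3.56 from the mean of single cells, which is also the ratio of the deposited signal, 3.55 without the cell with the most reads in each group, 3.64 with median ratio size factors, 3.12 with listed reads as the total, and 3.24 to 3.69 with each cell left out. The Alcam log2 ratio of −0.04 was −0.16, −0.37, 0.22 and −0.30 under the same settings in that order, and −0.61 to 0.20 with each cell left out. The cause of these shifts was not tested. Of the 86 other genes named, only Creld2 changed sign where its main interval excluded 0. Its log2 ratio of 0.20 was −0.0038 from the mean of single cells, −1.02 without the top cell of each group and −0.06 with listed reads as the total. The top cell of the with-MK group holds most of its reads, and the cause of the other reversals was not tested.

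Of 18 lists, 9 had a median above 0, against 13 on pooled levels and 8 to 10 under the other 8 settings, with 8 on the deposited signal. No list whose members' interval excluded 0 changed sign, except the respiratory chain list, which was at 0.23 on pooled levels. The cause was not tested. The median over all tested genes was −1.10, and it moved most on pooled levels (−0.14), with a pseudocount of 10 (−0.54) and on the deposited signal (−1.82). It was −0.90 with median ratio size factors and −1.27 with listed reads. Leaving out cells with 3 or more megakaryocyte genes could not be applied, since only 1 of the 20 is listed, and scran was not run. No paired analysis was possible because the numbers in the titles only count cells and no result comes from a test. Depth limits the shallow with-MK cells 11 and 16, in which 1 read is over 10 CPM.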

Other observations

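All tests of explanations in this part were chosen after the results were seen, and the genes singled out in its first 2 paragraphs were chosen after their values were seen. With-MK cells differed widely from each other in single genes, among them Mrc1, Pf4 and C1qb. The SD over cells of log2(CPM + 1) was 4.71, 4.54 and 4.00 for these, and 5.07 for Ccl7 and 4.21 for Bcl2l1. Whether any kind of gene varied more than others was not tested. Mrc1, the mannose receptor, stood above 1000 CPM in 8 of 20 cells and under 10 in 6. Pf4 stood above 1000 in 7 and under 10 in 5, and reached 8749. C1qb stood above 1000 in 8 and under 10 in 4. Adgre1, the gene of the F4/80 protein used in the sort, stood under 10 in 6 of 20 cells. Reads of Cd74, H2-Aa and H2-Ab1 came mostly from with-MK cell 6, which held 86.3% of the group's Cd74 reads, 99.7% of its H2-Aa reads and 94.0% of its H2-Ab1 reads, at 20287, 19638 and 8530 CPM. H2-DMa, another class II pathway gene, was spread over more cells, with reads in 15 of 20 and at most 931 CPM. Cell 16, one of the shallowest, also had 5350 CPM of H2-Ab1 and 2473 of Cd74, and more Mmp12 than cell 6, at 6901 and 4675. With-MK cell 2 held 39.1% of the Spp1 reads of its group.

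Without-MK cells differed among themselves in single genes too, among them Acta2 and Postn. The SD over cells of log2(CPM + 1) was 3.67 for Postn, and 4.36 for Ccl2 and 4.27 for Igf1. Whether genes of matrix and contraction varied more than others was not tested. The smooth muscle actin gene Acta2 stood above 1000 CPM in 6 of 24 cells and under 10 in 7, with 2 reads in all with-MK cells together. Postn stood above 1000 in 7 cells and under 10 in 4. Cell 13 held 56.1% of the group's Col1a2 reads, 34.9% of its Sparc reads and 57.9% of its Spp1 reads. Stem cell factor, Kitl, had reads in 10 of 24 without-MK cells, at 72.9 CPM, and in 2 of 20 with-MK cells, at 1.66, or 0.274 without cell 3, which held 84.6% of them. The monocyte-attracting chemokine gene Ccl2 was abundant in both groups, at 4394 and 2284 CPM in with-MK and without-MK cells. It stood above 1000 in 13 of 20 and 10 of 24 cells.

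The without-MK cells had few or no reads of most macrophage genes, Lgals3 (in 20 of 24 cells) and Cd68 (in 13) apart, and many of stromal genes, although they are labelled as sorted for CD45 and F4/80. Lower depth was tested by thinning every cell to 310000 reads. The median share of cells with a read over the 19 macrophage genes still differed by 79.8 percentage points (88.9% and 9.09%), which argues against it. A response to megakaryocytes among cells that are all macrophages would be expected to leave Ptprc or Adgre1 transcripts in the without-MK cells. Of these, 0 of 24 reached 10 CPM of either, against 19 of 20 with-MK cells. The exception, with-MK cell 7, had 31898 CPM of the macrophage list, so such transcripts can be low in a cell of that kind. Both genes belong to the macrophage list and their values were already known, so the count partly restates the pattern. Their reads also do not measure the sorted proteins. Stromal cells in the wells labelled without megakaryocytes, through the sort, the capture or the labels, stay open as an explanation without a test that could support it: 0 of 24 cells had more macrophage-list than stromal-list reads, which restates the pattern, and the plate is the same as the group. The sort is meant to remove such cells. All 24 without-MK cells lay below the lowest with-MK cell in macrophage-list CPM and above the highest in stromal-list CPM. On these lists their transcripts are stromal rather than macrophage in kind, Lgals3 and Cd68 apart. The table cannot say whether the sort, the capture or the labels brought this about.

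Emb was 10.4-fold higher in with-MK cells. A difference in cell type between the plates and a rise of Emb in macrophages through megakaryocytes cannot be told apart here. Either would have to be judged on without-MK cells with macrophage transcripts, and 0 of 24 had more macrophage-list than stromal-list reads. The similar Alcam level in both groups has the same limit, and is no check on a rise of Alcam in macrophages.

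The whole number that divides each gene's values was tested against 2 explanations. Annotated exon length had a Spearman correlation of −0.02 with it across 3472 genes, which argues against a length. The reads of another macrophage library, used in the place of a length, are a candidate explanation: the correlation with the mean level in with-MK cells was 0.39 across genes, against 0.19 for without-MK cells, and single with-MK cells ranged from 0.17 to 0.61 against the mean of the others. The without-MK value of 0.19 lies in that range too, so the range alone does not tell the groups apart. The numbers sum to 574119, within the 52076 to 929422 listed reads of a with-MK cell. That span is wide and also holds the listed reads of every without-MK cell, 170875 to 442967. Single genes go both ways. The 19 macrophage genes have from 1, in Csf1r and Aif1, to 6525, in Lgals3. The 5 stromal genes have 1 to 3, but Thbs1 has 3173 and Pdpn 989. Genes are not independent replicates in these correlations.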
